A study of Homo sapiens with 23 samples.

How the data were processed

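RNA of 13 muscle biopsies from patients with dermatomyositis and of 10 normal muscle biopsies was measured on Affymetrix U133 A arrays, 1 array per biopsy. The deposited values are linear signal intensities, never negative, with 1 intensity per probe set. On 20 arrays the mean without the lowest and highest 2% of probe sets was the same, 1499 to 1500 units, as a scaling to a common target would leave it, though the sources used here state no scaling. The arrays of normal 2, normal 3 and normal 6 had trimmed means of 102, 316 and 221 and are called unscaled. The program that summarized the probes, the RNA preparation and the scanner are not given in the sources used here. It therefore stays unknown which algorithm made the signals, when the arrays were run, why 3 differ in level, and whether treatment differed between patients. The labels name the diagnosis as the single factor, and the replicate numbers follow the order of deposition, so they pair no samples.

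The median deposited signal was 577, 535, 508, 576, 584, 571, 520.5, 586, 527.5, 565, 522, 557 and 523 on the arrays of dermatomyositis 1 to 13, and 549, 39, 108, 545, 591, 78.1, 608, 514, 575 and 471 on those of normal 1 to 10. An array gives no count of molecules, so the number of arrays limits the precision.

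The table held 22283 probe sets, of which 68 were controls. A single gene symbol was given for 19071 of the others, several for 1043 and none for 2107, and 52 probe sets of chromosome Y, XIST or TSIX were left out of every test and plot. Because the arrays were not uniformly scaled, signals were quantile-normalized, raised to a floor at the 10th percentile of positive values (49.5) and turned to log2. A probe set was tested if at least 10 of the 23 arrays exceeded the 40th percentile of all values (328), which kept 13809 probe sets, 12194 of them with a single gene. Each of 8359 genes was represented by its kept probe set with the highest mean. Of 2624 genes with more than 1 kept probe set, 123 had another that moved the opposite way at an unadjusted p under 0.05.

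Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and a fold of 2 as a second one, and 95% intervals from the moderated standard errors. The pipeline was tested on data simulated from each gene's mean and spread within groups, with 200 changed genes. It recovered 82% of changes of 1 and 100% of changes of 2 on the log2 scale, with 8 false among 190 calls. Simulated genes varied independently, with the same spread in both groups. Real genes did not all do so (ISG15: SD 3.09 in dermatomyositis, 0.71 in normal muscle), so the share of false calls in the real data was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

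Gene lists were written down before any value was seen: 38 lists, of which 37 had at least 3 genes to test. They covered type I interferon-inducible genes, interferon ligands, interferon receptors and sensors, interferon-gamma-associated genes, class I and class II antigen presentation, complement, chemokines, B cells, plasma cells, T cells, cytotoxic and natural killer cells, monocytes and macrophages, plasmacytoid and myeloid dendritic cells, neutrophils, mast cells, endothelium, smooth muscle and pericytes, fibroblasts and matrix, adipocytes, Schwann cells, red blood cells, core sarcomere, fast-fibre and slow-fibre genes, embryonic muscle and regeneration, muscle protein breakdown, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, fatty acid oxidation, endoplasmic reticulum stress, immediate early genes, hypoxia targets, metallothioneins, the cell cycle and ribosomal proteins. Between lists the shared genes were C1QA and C1QB, CCL19 and GZMB. Every list was tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, adjusted over the lists. With the estimated correlation no list kept its call, and fry, which tests whether a list's own genes move one way without comparing them with other genes, called the lists that camera called at the preset correlation except class II presentation and the matrix list (adjusted p = 0.105 and 0.163), and also neutrophils, hypoxia targets and the cell cycle. A biopsy's list score is the mean over tested members of the log2 signal minus the normal mean, compared by a permutation test of group means with 100000 resamples, or by exact enumeration where a group held fewer than 10 arrays. Correlations within dermatomyositis used Pearson's r and Spearman's rho with permutation p.

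The named genes follow a rule: the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a fold of at least 2, MX1, and per list up to 4 members past the threshold with the smallest p or, where no member passed, the brightest tested member (both members for plasmacytoid dendritic cells), given as a value. One of the 12 genes with the largest fall and a comparison of 4 control probe sets are not reported here. Immunoglobulin, HLA, IFITM, metallothionein and haemoglobin genes are uncertain, because their probe sets can share transcripts. The groups, tests, filter, floor, lists and this rule were fixed before the data were examined. So were alternatives with no scaling between arrays, median centring, no filter or a stricter one (60th percentile), floors at the 2nd and 30th percentiles, the mean of a gene's probe sets, array weights, the GAPDH 3 prime to 5 prime ratio as a covariate, a trended robust variance, each array left out in turn, and, for correlations, the 2 farthest patients left out. Chosen after seeing the data were trimmed mean scaling, the fits without the 3 unscaled arrays and without the 4 arrays whose ACTB control ratio exceeded 0, the class of that ratio as a block, and 3 further lists for the amino acid, glucocorticoid and p53 responses.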

Results

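Gene expression was measured in 13 muscle biopsies from patients with dermatomyositis, an inflammatory disease of muscle and skin, and in 10 from patients without a neuromuscular disorder, called normal here. Each biopsy was taken to come from a separate patient, which the labels do not state, and was hybridized to 1 Affymetrix U133 A array. The p-values of limma and of the permutation tests therefore rest on the spread between biopsies, and the number of arrays limits the precision. Those of camera at the preset correlation of 0.01 compare a list's genes with the other genes instead. The deposited table held 1 signal intensity per array for each of 22283 probe sets. The median signal ranged from 471 to 608 on 20 arrays whose trimmed means agreed, as after scaling to a common level. It was 39, 108 and 78.1 on the arrays of normal 2, normal 3 and normal 6, called unscaled here because their trimmed means lay far below. Signals were therefore quantile-normalized, and 8359 genes were tested. Terms that the submitters attached to the series (type I interferon, the antiviral protein MxA, plasmacytoid dendritic cells, innate immunity) give the question the comparison answers: which of these programmes differ in the diseased muscle.

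Dermatomyositis muscle had higher levels of antiviral interferon-inducible, class I antigen presentation, macrophage and stress genes. The list of embryonic muscle, regeneration and denervation genes was higher too, with 5 of 14 members past the threshold. Genes for mitochondrial respiration and sugar metabolism were lower, and so was the list of core sarcomere and muscle genes. A fall of the mitochondrial genes beyond that of muscle genes was not shown. The sugar metabolism genes were not compared with muscle genes. The list calls behind these statements were made with a preset correlation between members, and none was kept with an estimated one. In total 507 genes were higher and 499 were lower than in normal muscle (limma, adjusted p under 0.05). Of these, 187 and 53 changed at least 2-fold. The gene with the highest fold was ISG15 (probe set 205483_s_at), a ubiquitin-like protein attached to other proteins in the antiviral response, which rose 26.6-fold (95% interval 7.11 to 99.7, adjusted p = 0.0028) and lay above every normal biopsy in 10 of 13 patients. PSMB8 (209040_s_at), a catalytic subunit of the immunoproteasome, rose 21.9-fold (7.90 to 60.7, adjusted p = 0.0012). It lay above every normal biopsy in 10 patients, although 3 normal biopsies lay at the floor and the fold depends on it. CDKN1A (202284_s_at), the p21 inhibitor of the cell cycle, rose 9.99-fold (5.56 to 18.0, adjusted p = 0.000176), and POSTN (210809_s_at), the matrix protein periostin, rose 7.30-fold (4.10 to 13, adjusted p = 0.000419). Both were higher in 13 of 13 patients than in any normal biopsy. CDKN1A was lowest on the unscaled arrays of normal 2 and normal 3 (6.06 and 5.86). Without the 3 unscaled arrays its log2 difference was 2.65, against 3.32 with them (limma adjusted p = 0.000104 without them).

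The remaining genes among the 12 with the largest rises were antiviral or tied to immunity, muscle and stress. IGLV1-44, an immunoglobulin light chain segment, rose 11-fold, as did RSAD2, the antiviral enzyme viperin. MYH3, the embryonic myosin heavy chain, rose 9.37-fold. IFIT3, an antiviral protein of the interferon response, rose 9.01-fold, OAS1, a sensor of double-stranded RNA, 8.41-fold, and ISG20, an exonuclease, 7.52-fold. CHAC1, which degrades glutathione, rose 8.39-fold and SLC15A3, a lysosomal transporter of histidine and small peptides, 8.20-fold. The adjusted p of these 8 genes ranged from 0.0016 to 0.03, and 8 to 10 of 13 patients lay above every normal biopsy. IGLV1-44 is uncertain because immunoglobulin probe sets share transcripts, and 5 of its normal values lay at the floor. Among the 12 genes with the largest falls, TFRC, the transferrin receptor of iron uptake, was 3.18-fold lower, and MASP1, a protease of the lectin pathway of complement, 3.36-fold lower. PDP1, the phosphatase that activates pyruvate dehydrogenase, was 2.96-fold lower (2.01 to 4.36, adjusted p = 0.0016) and lay below every normal biopsy in 12 of 13 patients. ATP2B2, a plasma membrane calcium pump, was 2.97-fold lower, MYH4, a fast myosin heavy chain, 2.85-fold lower, DBP, a transcription factor of the circadian clock, 2.82-fold lower, and SLC38A3, a glutamine transporter, 2.81-fold lower. UPK3A (3.59-fold lower), OR7E47P (3.57-fold lower), LGI1 (3.23-fold lower) and EVX1 (2.73-fold lower) also belonged to this set, whose adjusted p ranged from 0.0016 to 0.0411.

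The 3 unscaled arrays were all normal, so no comparison within them was possible. Among the 20 arrays that shared a scaling, 247 genes were higher and 200 lower (limma). Of the genes named above, IGLV1-44, MYH3, UPK3A, TFRC, MYH4, DBP and SLC38A3 did not pass, with adjusted p from 0.0568 to 0.191. Without the 4 arrays (2 per group) whose ACTB control was stronger at the 3 prime than at the 5 prime end, 273 genes were higher and 273 lower. Of the genes named above, IGLV1-44, MYH3, UPK3A, LGI1, MYH4, DBP and SLC38A3 did not pass there (adjusted p from 0.0535 to 0.162). Among the 94 named genes past the threshold, 34 did not pass without the 3 unscaled arrays and 33 without these 4.

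**Figure D1:**
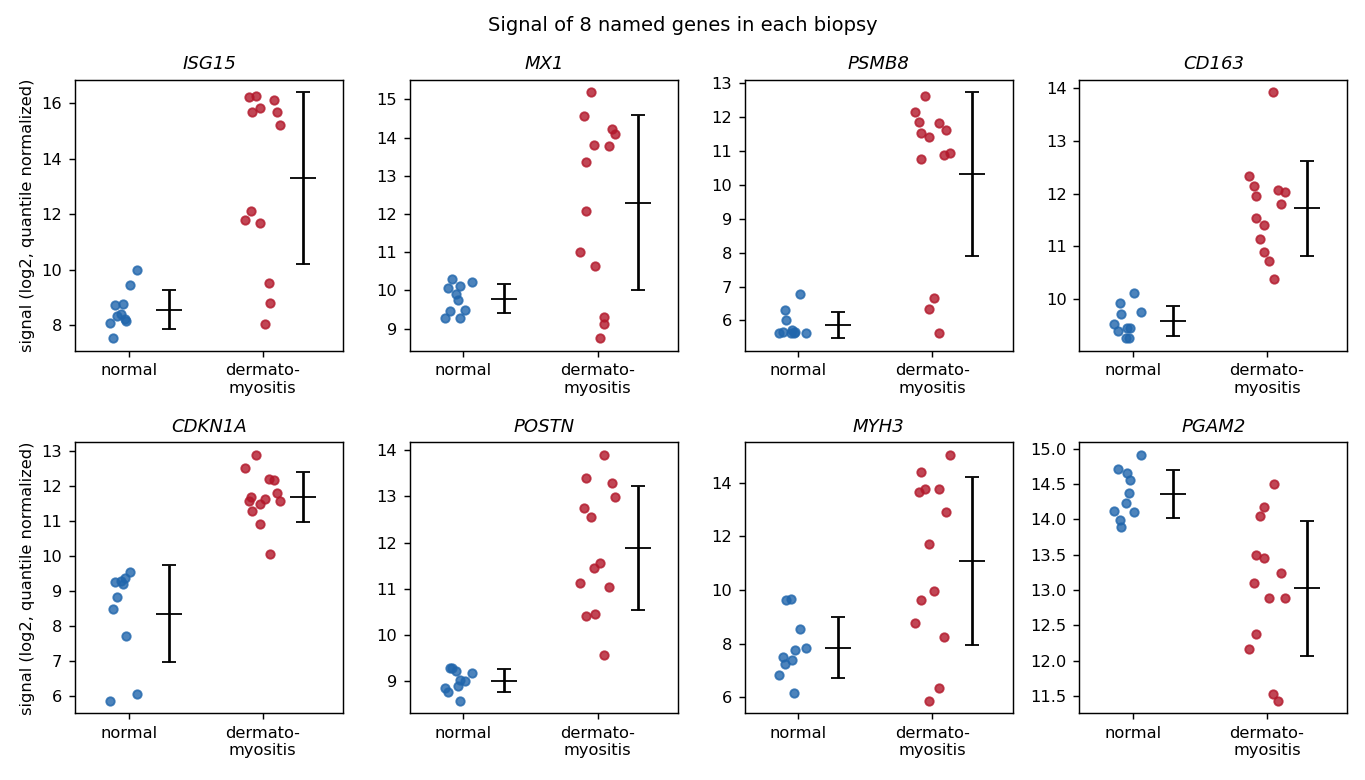
Log2 quantile-normalized signal of ISG15, MX1, PSMB8, CD163, CDKN1A, POSTN, MYH3 and PGAM2 in 13 dermatomyositis and 10 normal biopsies; each point is 1 biopsy, and bars give the mean ± SD. All 13 dermatomyositis points of CD163, CDKN1A and POSTN lie above every normal point, as do 10 points of ISG15, MX1 and PSMB8 each, and 10 points of PGAM2 lie below.

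Type I interferon-inducible genes, which cells switch on when interferon alpha or beta binds its receptor, showed the strongest shift of the lists. Of 40 members tested, 37 rose (32 without the 3 unscaled arrays), and 40 were higher when adjusted over the list alone. The median member was 1.88 higher on the log2 scale (camera adjusted p = 1.97e-31, adjusted p = 0.173 with an estimated correlation). UBE2L6, the conjugating enzyme for ISG15, rose 3.64-fold (adjusted p = 0.000713), SP100, a component of nuclear bodies, rose 3.26-fold (adjusted p = 0.000939), and IRF7, a transcription factor that drives interferon genes, rose 5.36-fold (adjusted p = 0.000939). IFITM1, which restricts the entry of viruses, rose 3.42-fold (adjusted p = 0.0016), but its probe sets can share transcripts with related genes. MX1, which encodes the MxA protein named by the submitters, rose 5.71-fold (2.17 to 15.0, adjusted p = 0.0176). MX1 lay above every normal biopsy in 10 patients and below every normal biopsy in 2. Its adjusted p was 0.0634 without the 3 unscaled arrays and 0.09 without the 4 arrays with a high ACTB ratio.

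The interferon score of a biopsy, the mean of its 40 log2 values relative to normal muscle, averaged 2.0 ± 1.33 (SD, n = 13) in dermatomyositis against 0.19 (SD, n = 10) around 0 in normal muscle (difference 2.0, 95% interval 1.12 to 2.88, permutation p = 0.00037, adjusted p = 0.0023 over 37 lists, two-sided). The score lay above every normal biopsy in 11 of 13 patients, and the patients spanned a range from -0.14 to 3.70. Among the 20 arrays with a common scaling the difference was 2.07 (exact permutation p = 0.0013, adjusted p = 0.0101).

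**Figure D2:**
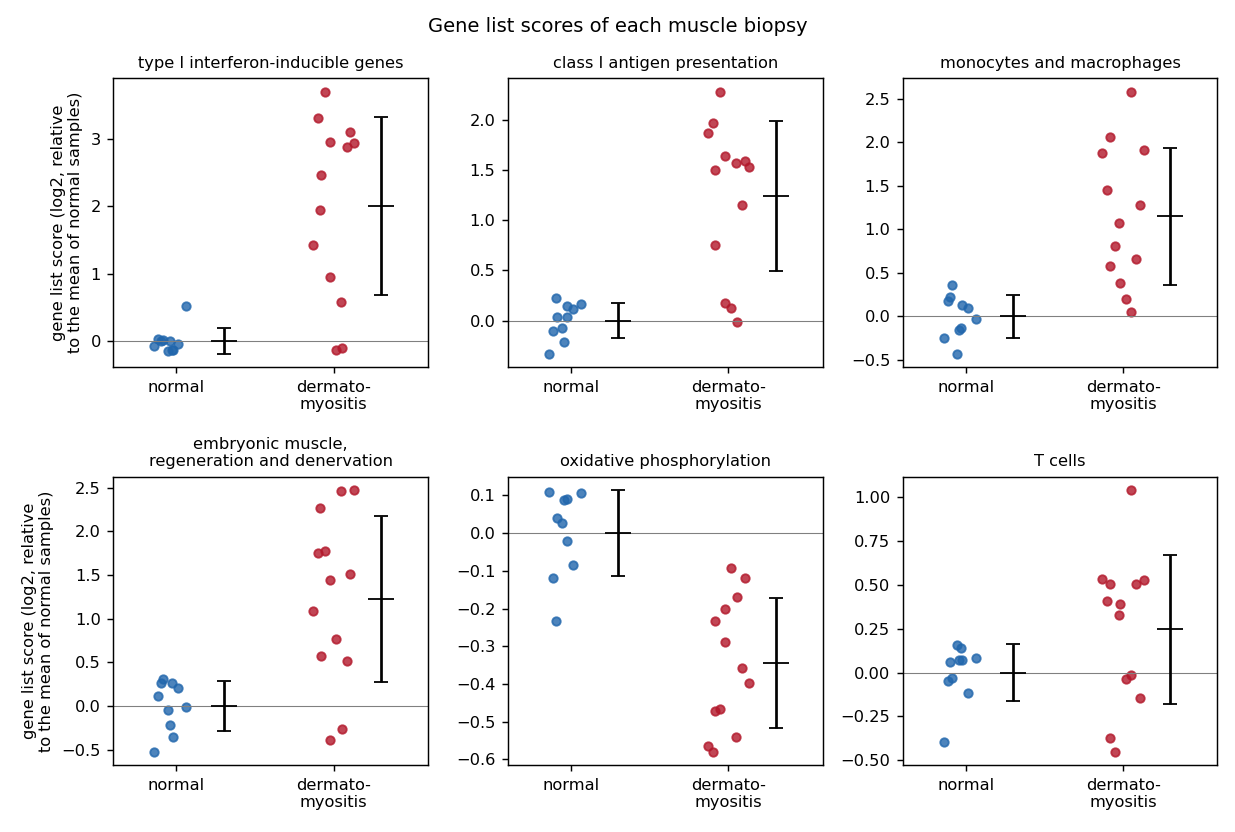
Scores of 6 gene lists per biopsy (mean log2 difference from the normal mean, 13 dermatomyositis, 10 normal); each point is 1 biopsy, and bars give the mean ± SD. The interferon score reaches 3.70 in dermatomyositis against 0.51 in normal muscle, and the oxidative phosphorylation score of 8 patients lies below every normal biopsy.

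For the genes of the interferons themselves a change was neither shown nor excluded, since most had too little signal to test. Of 15 listed ligand genes, 14 were on the array, and IFNA4, IFNA7, IFNA14, IFNA17 and IFNG were tested. Of these 5, 0 passed in limma or adjusted over the list alone (0 at an unadjusted p under 0.05, median -0.15, camera adjusted p = 0.489). IFNA17 differed by -0.28 on the log2 scale (adjusted p = 0.399), turning to 0.65 with no scaling between arrays. Among 12 interferon receptors and sensors, MYD88, an adaptor of Toll-like receptors, rose 1.78-fold (adjusted p = 0.0105), and JAK1, a kinase of interferon receptors, rose 1.26-fold (adjusted p = 0.041). Adjusted over the list alone, 4 members were higher and 1 lower. The lower one was IFNAR2, a chain of the type I interferon receptor (-0.38 on the log2 scale, limma adjusted p = 0.059). The other chain, IFNAR1, differed by -0.20 (limma adjusted p = 0.402). The median of the list was 0.27 (camera adjusted p = 0.0485, adjusted p = 0.173 with an estimated correlation). This call ended without dermatomyositis 1, 3, 7, 9, 10 or 11 or normal 5, 6 or 10, with adjusted p of up to 0.0866, and with no scaling (0.133), the stricter filter (0.0764), the GAPDH ratio as a covariate (0.0566) or the class of the ACTB ratio as a block (0.0563). JAK1 and MYD88 had adjusted p of 0.088 and 0.0563 without the 4 arrays with a high ACTB ratio. The score of the receptor and sensor list was higher by 0.23 (permutation adjusted p = 0.0015), with 10 of 13 patients above every normal biopsy. This score also passed without the 3 unscaled arrays and without the 4 arrays with a high ACTB ratio (exact permutation adjusted p = 0.0084 and 0.0081).

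Genes of the interferon-gamma-associated list moved the same way, which does not tell interferon gamma from type I interferon. IFNG itself differed by -0.15 on the log2 scale (limma adjusted p = 0.574). Of 10 tested, 5 rose (3 without the 3 unscaled arrays), and 7 were higher and 1 lower when adjusted over the list alone (median log2 difference 0.63, camera adjusted p = 0.000211, adjusted p = 0.173 with an estimated correlation). GBP1, a guanylate-binding protein of cell defence, rose 5.35-fold, its relative GBP2 rose 2.10-fold, and CXCL10, a chemokine that draws T cells, rose 4.34-fold. IRF8, a transcription factor of myeloid cells, rose 1.59-fold (adjusted p = 0.0308, and 0.0691 without the 3 unscaled arrays). CXCL10 had an adjusted p of 0.051 without the 4 arrays with a high ACTB ratio. Of the 5 members that did not pass, CXCL9 differed by 1.12 (limma adjusted p = 0.103) and SOCS1 by -0.75 (limma adjusted p = 0.108). The list's score was higher in 10 of 13 patients than in any normal biopsy.

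Genes of class I antigen presentation, which displays peptides from inside the cell to cytotoxic T cells, rose in 10 of 14 cases tested (8 without the 3 unscaled arrays), and 13 were higher when adjusted over the list alone. The median log2 difference was 1.04 (camera adjusted p = 1.65e-11, adjusted p = 0.173 with an estimated correlation), and the scores of 10 patients lay above every normal biopsy. HLA-B and HLA-C, the presenting molecules, rose 3.11-fold and 3.10-fold, though HLA probe sets can share transcripts. Their light chain B2M rose 1.77-fold (adjusted p = 0.0012), but did not pass with median or trimmed mean scaling. Class II presentation, used by macrophages, B cells and dendritic cells, had 1 of 10 genes past the threshold and 2 adjusted over the list alone. CTSS, the protease that trims the invariant chain, rose 1.99-fold (adjusted p = 0.0202, and 0.0603 without the 3 unscaled arrays). The list was called higher (median 0.48, camera adjusted p = 0.0051), with an adjusted p = 0.396 with an estimated correlation. Its score did not pass (difference 0.51, permutation adjusted p = 0.11, 6 of 13 patients above every normal biopsy).

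Monocyte and macrophage genes rose in 9 of 17 cases (7 without the 3 unscaled arrays), and in 13 adjusted over the list alone (median log2 difference 0.96, camera adjusted p = 1.65e-11, adjusted p = 0.173 with an estimated correlation). CD163, the scavenger receptor for haemoglobin on macrophages, rose 4.37-fold (2.94 to 6.51, adjusted p = 0.000239) and was higher in all 13 patients than in any normal biopsy. VSIG4, a complement receptor of tissue macrophages, rose 2.91-fold, and SIGLEC1, a macrophage lectin that interferon also induces, rose 1.70-fold. The macrophage score exceeded every normal biopsy in 11 patients. Complement genes, part of innate defence, rose in 9 of 13 cases (5 without the 3 unscaled arrays) and in 11 adjusted over the list alone (median 0.99, camera adjusted p = 6.73e-09, adjusted p = 0.173 with an estimated correlation). C1QA and C1QB, chains of the initiating C1q complex that the macrophage list also holds, rose 5.42-fold and 3.57-fold, C3AR1, the receptor for the C3a fragment, rose 2.77-fold, and SERPING1, the C1 inhibitor, rose 1.91-fold. Of 11 chemokines and receptors, 4 rose (3 without the 3 unscaled arrays) and 7 were higher adjusted over the list alone (median 0.72, camera adjusted p = 0.000272, adjusted p = 0.173 with an estimated correlation). CCL2, which draws monocytes, rose 4.78-fold, CCL18, made by macrophages, 2.75-fold, the receptor CCR1 2.30-fold and CCL5, which draws T cells, 1.64-fold. With the stricter filter the chemokine call ended (adjusted p = 0.498). CCL18 and CCL5 did not pass without the 4 arrays with a high ACTB ratio (adjusted p = 0.101 and 0.0562).

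Plasma cell genes, mostly immunoglobulins, had 2 of 9 members past the threshold, and 2 adjusted over the list alone. IGKC rose 3.06-fold and IGLC1 5.19-fold, both uncertain because of shared transcripts and with adjusted p of 0.0691 and 0.0764 without the 3 unscaled arrays. The list was called higher (median 0.33, camera adjusted p = 0.0372, adjusted p = 0.239 with an estimated correlation), with 7 of 13 scores above every normal biopsy. This call ended without the 3 unscaled arrays (0.0971), the 4 arrays with a high ACTB ratio (0.0727), without dermatomyositis 7 (0.0529), dermatomyositis 9 (0.0604) or normal 3 (0.0536), and with the stricter filter (0.0868). Of 15 listed T cell genes on the array, 9 had enough signal to test. Of these 9, 0 passed in limma or adjusted over the list alone (2 were higher at an unadjusted p under 0.05). The T cell score differed by 0.25 (95% interval -0.05 to 0.54, permutation adjusted p = 0.153). It lay above every normal biopsy in 8 of 13 patients and below in 1. A change of T cell genes was thus neither shown nor excluded. TRBC1, the T cell receptor beta constant region, differed by 0.23 on the log2 scale. Among 7 genes of cytotoxic and natural killer cells 0 passed in limma or over the list alone (1 higher at an unadjusted p under 0.05), with 0.45 for PRF1, the pore protein perforin. B cell genes likewise had 0 of 5 past the threshold in limma or over the list alone (1 lower at an unadjusted p under 0.05), with -0.41 for TCL1A, turning to 0.49 with no scaling. The camera adjusted p of these 3 lists was 0.176, 0.488 and 0.489, and their medians were 0.10, 0.17 and -0.02.

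Plasmacytoid dendritic cells, the main producers of interferon alpha, were barely measurable here, since 6 of the 9 listed markers were on the array and 2 of these had enough signal to test. PTCRA differed by -0.20 (adjusted p = 0.50), turning to 0.73 with no scaling. GZMB, shared with cytotoxic cells, differed by 0.47 (adjusted p = 0.38). In limma 0 of 2 passed, with 0 at an unadjusted p under 0.05. Myeloid dendritic cell genes had 0 of 7 past the threshold in limma or over the list alone (2 higher at an unadjusted p under 0.05, median 0.06, camera adjusted p = 0.437). CD1A differed by -0.10, turning to 0.81 with no scaling and 0.11 without the 3 unscaled arrays. Neutrophil genes had 0 of 6 past the threshold in limma and 2 higher adjusted over the list alone (median 0.29, camera adjusted p = 0.0861). S100A8 differed by 0.95 and is a calcium-binding protein of neutrophils and monocytes. This list passed camera without normal 1 (0.0468) or normal 7 (0.0299) and with the stricter filter (0.0371). Its score differed by 0.36 (permutation adjusted p = 0.0485, 2 of 13 above every normal biopsy), but not without the 3 unscaled arrays (exact permutation adjusted p = 0.131). Mast cell genes had 0 of 4 past the threshold in limma or over the list alone (0 at an unadjusted p under 0.05, median 0.06, camera adjusted p = 0.673). TPSAB1, a tryptase, differed by 0.06.

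Genes of embryonic muscle, regeneration and denervation, which adult fibres express when they rebuild or lose their nerve, rose in 5 of 14 cases (2 without the 3 unscaled arrays) and in 8 adjusted over the list alone. The median log2 difference was 1.12 (camera adjusted p = 4.82e-05, adjusted p = 0.173 with an estimated correlation), and 11 of 13 scores lay above every normal biopsy. CHRNA1 and CHRND, subunits of the acetylcholine receptor of the neuromuscular junction, rose 4.10-fold and 2.78-fold. MYH3 (9.37-fold) belongs to this list, as does CDKN1A (9.99-fold), which halts the cycle of differentiating muscle cells but is induced by stress as well. MYH3 did not pass without dermatomyositis 6, normal 3 or normal 9, with adjusted p of up to 0.0535, and CHRND had an adjusted p of 0.128 without the 3 unscaled arrays. Of 12 genes of muscle protein breakdown, 1 rose and 4 were higher adjusted over the list alone. CBLB, a ubiquitin ligase, rose 1.74-fold (adjusted p = 0.0057, above every normal biopsy in 10 patients). The list was called (median 0.23, camera adjusted p = 0.0405, adjusted p = 0.277 with an estimated correlation). It was not without dermatomyositis 1, 2, 3 or 11, normal 2, 5, 6 or 9, or the 3 unscaled arrays (adjusted p of up to 0.0853), nor with median, trimmed mean or no scaling (0.0825, 0.0622 and 0.363) or the mean of probe sets (0.0634). Its score did not pass (0.14, permutation adjusted p = 0.18).

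Core sarcomere and muscle genes fell in 4 of 19 cases (9 with median and 10 with trimmed mean scaling, 2 without the 3 unscaled arrays), and in 5 adjusted over the list alone. SGCA, a sarcoglycan of the fibre membrane, CAPN3, the muscle calpain, DMD, which encodes dystrophin, and MYOM2, a protein of the M-band, were 1.57-fold, 1.63-fold, 1.58-fold and 1.5-fold lower. The median was -0.16 (camera adjusted p = 0.002, adjusted p = 0.239 with an estimated correlation) and -0.59 with median scaling. Quantile normalization gives the brightest genes of every array the same values. Ribosomal protein genes, also bright, were likewise called lower with median and trimmed mean scaling (medians -0.33 and -0.32). The larger falls with those scalings in this paragraph are therefore not particular to muscle genes. DMD and MYOM2 did not pass without the 3 unscaled arrays (adjusted p = 0.0528 and 0.0689). Of 12 fast-fibre genes, 1 fell (4 with median and 6 with trimmed mean scaling, 0 in limma without the 3 unscaled arrays), with 1 adjusted over the list alone. MYH4 was 2.85-fold lower, and the list was called (median -0.42, camera adjusted p = 0.0146, adjusted p = 0.294 with an estimated correlation). Both the MYH4 call (adjusted p = 0.191) and the fast-fibre call (0.0711) ended without the 3 unscaled arrays, as they did without the 4 arrays with a high ACTB ratio (0.162 and 0.059), and the score did not pass (-0.47, permutation adjusted p = 0.0538). Of 10 slow-fibre genes, 1 fell, with 2 adjusted over the list alone. ATP2A2, the calcium pump of slow fibres, was 1.24-fold lower (adjusted p = 0.0332, below every normal biopsy in 11 patients), with an adjusted p of 0.0682 without the 3 unscaled arrays. The slow-fibre list was not called (median -0.17, camera adjusted p = 0.153), but was with median (median -0.65, adjusted p = 0.0013), trimmed mean (0.0012) or no scaling (0.000319).

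Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, fell in 17 of 38 cases (27 with median and 31 with trimmed mean scaling, 4 without the 3 unscaled arrays), and in 29 adjusted over the list alone (median log2 difference -0.37, camera adjusted p = 3.62e-12, adjusted p = 0.173 with an estimated correlation). The larger counts with median and trimmed mean scaling, here and in the other energy lists, are not particular to energy genes. Ribosomal protein genes, also bright, were called lower with those scalings too (medians -0.33 and -0.32). ATP5MC1 of ATP synthase was 1.46-fold lower, NDUFA9 of complex I 1.36-fold lower, and UQCRB and UQCRC2 of complex III 1.33-fold and 1.30-fold lower (adjusted p = 0.0054 to 0.0138). The score fell by 0.34 (95% interval -0.48 to -0.21, permutation p = 5e-05, adjusted p = 0.0015), with 8 of 13 patients below every normal biopsy. Tricarboxylic acid cycle genes fell in 6 of 14 cases (9 with median and 8 with trimmed mean scaling, 1 without the 3 unscaled arrays), with 6 adjusted over the list alone (median -0.31, camera adjusted p = 0.002, adjusted p = 0.239 with an estimated correlation). IDH3B, a subunit of isocitrate dehydrogenase, was 1.5-fold lower, SUCLG1 and SUCLA2 of succinyl-CoA ligase 1.33-fold and 1.35-fold lower, and MDH2, malate dehydrogenase, 1.29-fold lower. The cycle's score did not pass (-0.21, permutation adjusted p = 0.0543, 4 of 13 patients below every normal biopsy). UQCRB, UQCRC2, SUCLG1, SUCLA2 and MDH2 did not pass without the 3 unscaled arrays (adjusted p = 0.0566 to 0.0751).

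Glycolysis and glycogen genes fell in 5 of 19 cases (11 with median and 13 with trimmed mean scaling, 1 without the 3 unscaled arrays) and in 8 adjusted over the list alone (median -0.37, and -0.62 with median scaling, camera adjusted p = 3.49e-05, adjusted p = 0.218 with an estimated correlation), and 10 of 13 scores lay below every normal biopsy. PGAM2, the muscle phosphoglycerate mutase, was 2.52-fold lower (1.64 to 3.86, adjusted p = 0.0064), FBP2, the muscle fructose bisphosphatase, 2.60-fold lower, ENO3, the muscle enolase, 1.55-fold lower, and PHKB, a subunit of phosphorylase kinase, 1.5-fold lower. Fatty acid oxidation genes fell in 2 of 21 cases and in 1 adjusted over the list alone (median -0.28, camera adjusted p = 0.0016, adjusted p = 0.277 with an estimated correlation). ACADM, the medium-chain acyl-CoA dehydrogenase, was 1.77-fold lower (adjusted p = 0.0044), and ETFDH, which passes its electrons to the respiratory chain, 1.43-fold lower (adjusted p = 0.0461). The score did not pass (-0.29, permutation adjusted p = 0.0867). FBP2, ENO3, PHKB and ETFDH did not pass without the 3 unscaled arrays (adjusted p = 0.0691 to 0.114). With no scaling between arrays the median gene was 0.87 higher, and the medians of the muscle and energy lists that were lower turned positive (0.20 to 0.61) but stayed below that shift.

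**Figure D3:**
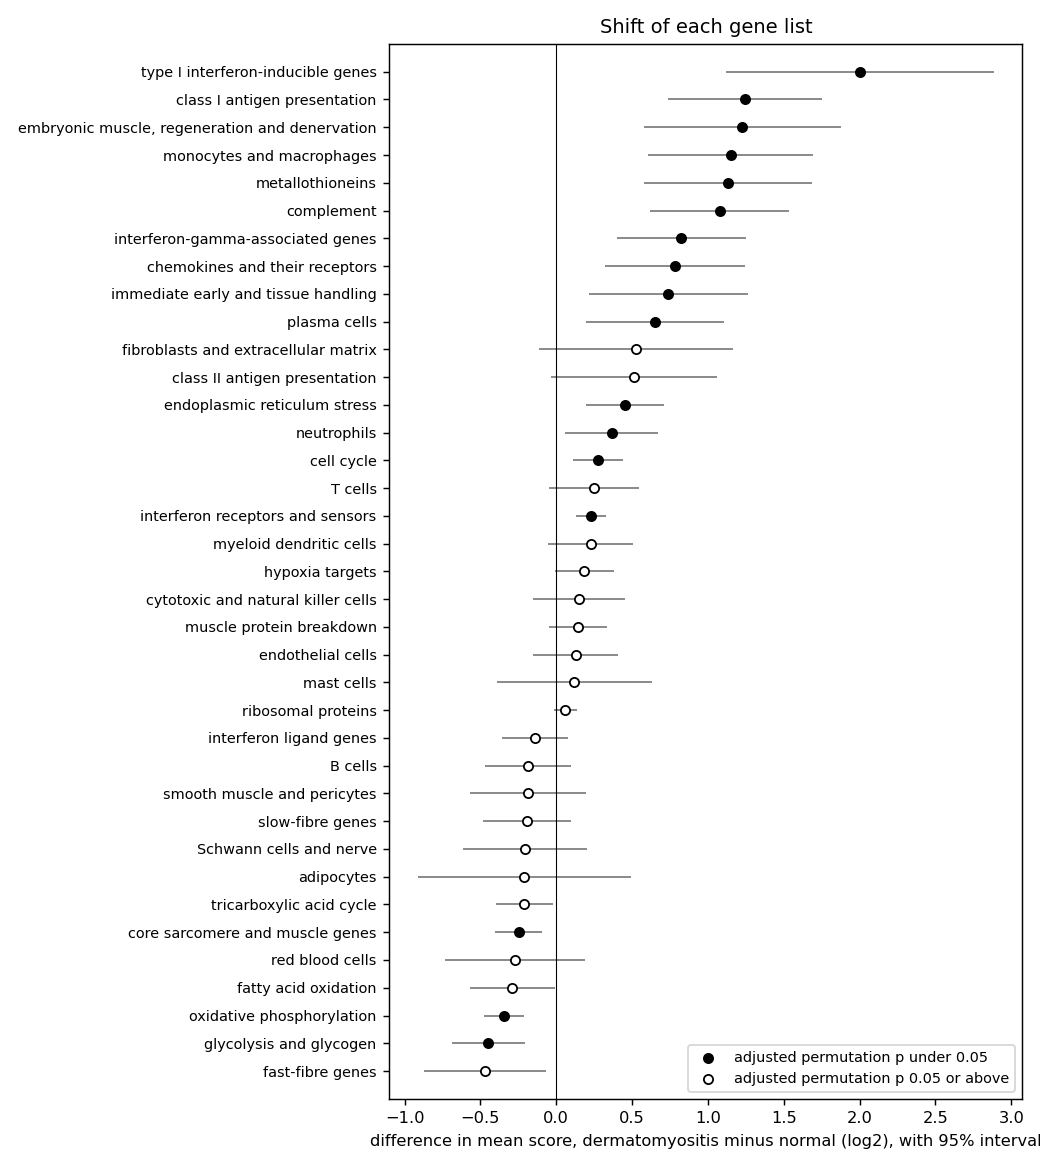
Difference in score between 13 dermatomyositis and 10 normal biopsies for 37 gene lists, in log2 units; points are differences, bars are 95% intervals, and filled points have a permutation adjusted p under 0.05. Type I interferon-inducible genes lie farthest to the right (2.0) and glycolysis and oxidative phosphorylation genes lie to the left of 0 (-0.45 and -0.34).

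Several stress programmes were higher. Metallothioneins, small proteins that bind zinc and copper, rose in 6 of 8 cases (4 without the 3 unscaled arrays) and in 7 adjusted over the list alone (median 1.34, camera adjusted p = 1.44e-05, adjusted p = 0.173 with an estimated correlation). MT1E rose 2.59-fold, MT1M 3.55-fold, MT2A 2.87-fold and MT1F 2.65-fold, all uncertain because their probe sets share transcripts, and 10 of 13 scores lay above every normal biopsy. Endoplasmic reticulum stress genes rose in 3 of 16 cases (2 without the 3 unscaled arrays) and in 5 adjusted over the list alone (median 0.31, camera adjusted p = 0.0021, adjusted p = 0.173 with an estimated correlation), also with 10 of 13 scores above every normal biopsy. ASNS, which makes asparagine and also responds to a lack of amino acids, rose 4.79-fold (adjusted p = 0.0051), SDF2L1, an endoplasmic reticulum protein, 1.79-fold, and HSPA5, the chaperone BiP, 1.35-fold (adjusted p = 0.0488, and 0.0838 without the 3 unscaled arrays). Immediate early genes, which also respond to the handling of tissue, rose in 4 of 12 cases (1 without the 3 unscaled arrays) and in 5 adjusted over the list alone (median 0.67, camera adjusted p = 0.0016, adjusted p = 0.239 with an estimated correlation). MYC, a transcription factor of growth, rose 5.18-fold (adjusted p = 0.0039), IER2 1.81-fold, DUSP1, a phosphatase of MAP kinases, 1.63-fold, and KLF6, a zinc finger transcription factor, 1.83-fold. Without the 3 unscaled arrays IER2, DUSP1 and KLF6 did not pass (adjusted p = 0.123 to 0.228), nor did the list's score (exact permutation adjusted p = 0.122).

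The hypoxia list was not called (median 0.17, camera adjusted p = 0.146), but 2 of 8 members passed the threshold, and 3 adjusted over the list alone. ADM, the vasodilator adrenomedullin, rose 1.69-fold (adjusted p = 0.0029), and HIF1A, the hypoxia-inducible factor, 1.61-fold (adjusted p = 0.025, and 0.0531 without the 3 unscaled arrays). Cell cycle genes had 1 of 13 past the threshold, also adjusted over the list alone. MCM5, a subunit of the replicative helicase, rose 3.30-fold (adjusted p = 0.0024, above every normal biopsy in 4 patients). The cell cycle score was higher by 0.28 (permutation adjusted p = 0.0043, 6 of 13 above every normal biopsy). Camera did not call the list (median 0.24, adjusted p = 0.0776) except with median scaling (0.0461), no filter (0.009) or without the 4 arrays with a high ACTB ratio (0.0442). Ribosomal protein genes had 0 of 17 past the threshold in limma or over the list alone (2 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.489). Their median of 0.01 turned to -0.33 with median and -0.32 with trimmed mean scaling, where the list was called lower. RPL7 differed by 0.07, turning to -0.33 and -0.32 with those scalings.

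Fibroblast and extracellular matrix genes rose in 3 of 23 cases (2 without the 3 unscaled arrays), with 3 adjusted over the list alone. These were POSTN (7.30-fold), TIMP1, an inhibitor of matrix proteases (2.82-fold, adjusted p = 0.0105, and 0.0655 without the 4 arrays with a high ACTB ratio), and TNC, the matrix protein tenascin (1.79-fold, adjusted p = 0.0499, and 0.0919 without the 3 unscaled arrays). The list was called higher (median 0.39, camera adjusted p = 0.0016, adjusted p = 0.491 with an estimated correlation), but its score did not pass (0.53, permutation adjusted p = 0.156, 7 of 13 above and 2 below every normal biopsy). Endothelial genes were not called (median 0.10, camera adjusted p = 0.489). Of 17, 1 rose, with 1 adjusted over the list alone. This was TIE1, a receptor kinase of vessels (2.71-fold, adjusted p = 0.0282, and 0.0531 without the 3 unscaled arrays). Of 9 smooth muscle and pericyte genes, MCAM, an adhesion molecule of vessels, rose 1.71-fold (adjusted p = 0.024, and 0.105 without the 3 unscaled arrays), and RGS5, a regulator of pericyte signalling, was 1.58-fold lower (adjusted p = 0.011). Adjusted over the list alone, 1 was higher and 2 lower (median -0.30, camera adjusted p = 0.463). MBP, myelin basic protein, was 2.04-fold lower (adjusted p = 0.0032, below every normal biopsy in 11 patients). It was the member past the threshold, also adjusted over the list alone, among 4 Schwann cell genes (median -0.10, camera adjusted p = 0.437). Adipocyte genes had 0 of 6 past the threshold in limma or over the list alone (1 lower at an unadjusted p under 0.05, median -0.31, camera adjusted p = 0.556). FABP4, the fatty acid carrier, differed by 0.25, turning to -0.0085 without the 3 unscaled arrays. Red cell genes had 0 of 4 in limma or over the list alone (0 at an unadjusted p under 0.05, median -0.27, camera adjusted p = 0.434). HBB, a haemoglobin chain, differed by -0.31, turning to 0.24 with no scaling.

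Within the 13 dermatomyositis biopsies, whose arrays shared a scaling, 10 relations of the interferon score with other scores were tested. It went with class I antigen presentation (Pearson r = 0.73, permutation p = 0.0054, adjusted p = 0.0542, Spearman rho = 0.75, permutation p = 0.0042, adjusted p = 0.0422). Without the 2 patients farthest from the median interferon score r was 0.47 (permutation p = 0.143) and rho 0.60 in the other 11. Neither macrophage (r = 0.20, rho = 0.28), T cell (r = -0.21, rho = -0.27), plasma cell (r = 0.50, rho = 0.49), endothelial (r = -0.18, rho = -0.27) nor matrix scores (r = 0.31, rho = 0.36) gave a relation that passed, with permutation p from 0.0831 to 0.547 for r and from 0.0896 to 0.373 for rho. Nor did regeneration (r = 0.43, rho = 0.40), fast-fibre (r = 0.03, rho = 0.13), oxidative phosphorylation (r = -0.25, rho = -0.25) or core sarcomere scores (r = -0.33, rho = -0.32), with p from 0.146 to 0.924 for r and from 0.176 to 0.672 for rho. The adjusted p of these 9 relations was at least 0.415 for r and 0.448 for rho. The largest gap between neighbouring interferon scores was 0.68 in a range of 3.84.

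Measures of RNA and array quality were compared between the groups. The log2 ratio of the 3 prime to the 5 prime control probe sets, a measure of RNA degradation, was -0.15 ± 0.35 in dermatomyositis and -0.15 ± 0.18 in normal muscle for GAPDH (SD, permutation p = 0.983) and -0.16 ± 0.50 and -0.49 ± 0.46 for ACTB (permutation p = 0.13, adjusted p = 0.195). With trimmed mean scaling 10.2% and 9.76% of signals lay at the floor (permutation p = 0.5, adjusted p = 0.6). The mean correlation of an array with the others of its group was 0.892 ± 0.014 in dermatomyositis and 0.912 ± 0.013 in normal muscle (SD). Its permutation p was 0.0027 (adjusted p = 0.0118). Arrays of a group share pairs, and the correlations were not recomputed for each resample. This p therefore does not test a difference in spread. Deposited medians averaged 550.1 and 408 (adjusted p = 0.0695) and upper quartiles 1627 and 1164 (adjusted p = 0.0118), which follows from the 3 unscaled normal arrays.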

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

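The leukocyte test, the fits with the ACTB ratio, the test of macrophage against endothelial scores, the range by normal means for core muscle genes and the count of genes at an unadjusted p were chosen after the result was seen; the other tests of this part were set down before.

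Probe sets that name no single gene were left out of the gene comparison, and 134 of the 1615 tested passed the threshold in limma, 60 higher and 74 lower.

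Among the 10 normal biopsies, 1 biopsy stood apart from the other 9 in 12 of 145 list scores, named genes and array measures, by a gap that is large for the whole range (Dixon's 95% critical value). Chance alone gives about 1 in 20. The type I interferon score of normal 2 was the highest, 0.51 against at most 0.03 in the others (gap 0.728 of the range). The adipocyte score of normal 7 was 1.68 against at most 0.35 (0.527), the lowest T cell score was that of normal 3 (0.509), the lowest endothelial score that of normal 5 (0.477) and the lowest cell cycle score that of normal 9 (0.53). CHAC1 was highest in normal 10 (0.692) and SERPING1 in normal 7 (0.588). The lowest values of MASP1 were in normal 5 (0.528), of CCL5 in normal 9 (0.65), of TRBC1 in normal 3 (0.598), of TNC in normal 10 (0.559) and of HSPA5 in normal 9 (0.487). The arrays of normal 2 and normal 3 were unscaled, and that of normal 3 also had a high ACTB ratio. Those of normal 5, 7, 9 and 10 were neither unscaled nor high in that ratio. No explanation was tested for these single biopsies.

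Chance was tested by splitting the 23 samples at random into groups of 13 and 10, 100 splits with the real one. Of these, 1, the real one, gave as many genes for the 507 higher genes (highest other 1), the 499 lower (highest other 0), the 187 at least 2-fold higher (highest other 0) and the 53 at least 2-fold lower (highest other 0), so chance can be excluded for the counts of genes. For the 15 lists called higher 2 of 100 splits gave as many, the real one and another that gave 16. Other random splits called 16 and 15 lists lower. The number of lists called higher therefore does not exclude chance. At least 6 lower lists came from 19 of 100 splits (highest other 16), so chance is not excluded for that number either. Splits with at most 1 gene in either direction called up to 16 lists, which points to list members that vary together. Many did so around the group means, where camera, with both groups pooled, estimated a correlation between members from -0.0153 for interferon receptors and sensors to 0.76 for type I interferon-inducible genes.

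Interferon-inducible genes were higher in dermatomyositis by a score of 2.0. Fitted together with the macrophage, T cell and plasma cell scores the difference was 1.51 (95% interval 0.50 to 2.52), so these 3 scores did not account for all of it. The T cell and plasma cell scores rest on 9 genes each, and other leukocytes were not in the fit. It therefore cannot exclude RNA of infiltrating leukocytes as the whole source. The GAPDH 3 prime to 5 prime ratio, planned as the measure of RNA degradation, was alike in both groups (difference 0.0039), so a fit with it tests nothing. The ACTB ratio differed by 0.32 and went with 383 genes past the threshold. With it in the fit 717 of the 1006 gene calls were kept, and the interferon difference was 1.83 (0.90 to 2.76). Without the 3 unscaled arrays it was 2.07 (1.0 to 3.13). These values argue against degradation as that ratio measures it, and against those arrays, as the whole cause. The interferon score had no detected slope on the ratio (linear fit, p = 0.249), so degradation that the ratio misses stays open. A response of the tissue to interferon may underlie these genes, as a hypothesis found and tested on the same data. Which cells made the RNA, infiltrating leukocytes among them, and treatment stay open.

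Oxidative phosphorylation genes were lower by a score of -0.34. RNA degradation as the ACTB ratio measures it and the 3 unscaled arrays are argued against as the whole cause. The difference was -0.33 (-0.48 to -0.19) with that ratio in the fit and -0.33 (-0.48 to -0.18) without those arrays. This score had no detected slope on the ratio (linear fit, p = 0.63), so degradation that the ratio misses stays open. A lower share of muscle-fibre RNA in the biopsies may account for the lower mitochondrial genes. The mean of 7 core muscle genes whose normal means lay in the range of the mitochondrial genes was lower by 0.39 (-0.63 to -0.15), with 3 of the 7 past the threshold. The mitochondrial score minus theirs was 0.0450 (-0.17 to 0.26). This value depends on the genes chosen. It was 0.20 (-0.005 to 0.40) against the 7 core genes no brighter, over all arrays, than the brightest mitochondrial gene, and -0.10 (-0.26 to 0.06) against all 19 core genes. A fall of the mitochondrial genes beyond that of muscle genes was thus not shown, nor was it ruled out. The macrophage score rose by 1.02 (0.57 to 1.46) more than the endothelial score. If these scores follow the shares of the cells, this argues against the form of the explanation in which all other cell types rise alike. Whether they do was not tested, and SIGLEC1 and CD163 of the macrophage list can also be induced. A growth in macrophage RNA, or a change inside the fibres, stays open and was not tested.

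Fewer genes passed without the 3 unscaled normal arrays, 447 against 1006. A loss of samples may account for it, since leaving out 100 other sets of 3 normal arrays gave 378 to 807 genes. A different profile of the unscaled arrays cannot be told apart from none. Against the other 7 normal arrays they gave 0 genes in limma, but so did 77 of 100 other sets of 3. At an unadjusted p under 0.05 they gave 455 genes, and 22 of the 100 sets gave as many (median 311.5, highest 1654), which neither shows nor excludes one. Batch and diagnosis cannot be separated for these 3 arrays, which hold 1 group alone; no biological explanation was tested.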

How the results depend on the processing

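Trimmed mean scaling, the fits without the 3 unscaled arrays and without the 4 arrays with a high ACTB ratio, and that ratio as a block were chosen after seeing the data. The type I interferon score kept its direction and passed in every alternative run, from 1.83 without the 4 arrays to 2.90 with no scaling. All 1006 genes past the threshold kept their direction in each fit that left out samples. Because these fits share most arrays with the fit that chose the genes, this is weak evidence. With no scaling the median gene was 0.87 higher by construction, 1785 genes were higher, 1785 of them at least 2-fold, and 0 were lower in limma (1 at an unadjusted p under 0.05) or at least 2-fold lower (0). Without the 3 unscaled arrays 247 genes were higher, 124 at least 2-fold, and 200 lower, with 429 of the 1006 calls kept; without the 4 arrays 273 were higher and 273 lower, 32 at least 2-fold, with 499 kept. Both have fewer samples. The stricter filter tested fewer genes and gave 124 at least 2-fold higher. Leaving out single arrays gave 383 to 637 genes higher, 362 to 632 lower, 161 to 218 at least 2-fold higher and 35 to 68 at least 2-fold lower (35 without dermatomyositis 6), with 13 to 16 lists higher and 6 lower; the interferon score ranged from 1.86 to 2.18. With an estimated correlation, which counts members that vary together as less evidence, camera called 0 lists higher and 0 lower (8 of the 15 and 1 of the 6 had an unadjusted p under 0.05).

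Correlations of the interferon score changed without the 2 farthest patients, to 0.47 for class I presentation, -0.35 for macrophages, -0.62 for T cells (permutation p = 0.0429, not adjusted) and 0.23 for oxidative phosphorylation, and with median centring to 0.0708 for oxidative phosphorylation and 0.0436 for core sarcomere genes; the cause was not tested.

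Of the 94 named genes past the threshold, 34 did not pass without the 3 unscaled arrays, 33 without the 4 arrays, 40 in either, and 19 in at least 1 fit that left out an array. With no scaling, log2 differences turned positive by the same shift: IFNA17 0.65, TCL1A 0.49, PTCRA 0.73, CD1A 0.81, RGS5 0.17, HBB 0.24, SGCA 0.26, DMD 0.20, MYOM2 0.0559, ATP2A2 0.22, ATP5MC1 0.33, UQCRB 0.29, NDUFA9 0.42, UQCRC2 0.36, IDH3B 0.26, SUCLG1 0.40, SUCLA2 0.43, MDH2 0.35, PHKB 0.30, ACADM 0.0105 and ETFDH 0.41, all still below the median gene. Without the 3 unscaled arrays CD1A turned to 0.11 and FABP4 to -0.0085. TPSAB1 turned to -0.0065 with the ratio as a block, and to -0.0794 as the lowest value with 1 array left out. RPL7 turned to -0.33 with median centring, -0.32 with trimmed mean scaling and -0.0336 with the mean of its probe sets; the cause of these was not tested. The calls of MYH3 ended without dermatomyositis 6, normal 3 or normal 9 (adjusted p up to 0.0535), of TIE1 without normal 4, 5 or 9 (0.0548), of IRF8 without dermatomyositis 6 or 10 or normal 4 or 7 (0.0574), of CCL5 without dermatomyositis 5, 6 or 12 or normal 4 (0.0595), of ATP2A2 without dermatomyositis 5, 6 or 9 or normal 7, 9 or 10 (0.0594) and of IER2 without dermatomyositis 4, 6 or 10 or normal 3, 8 or 10 (0.061). Those of UPK3A, DBP, MYOM2, CHRND, MYH4, JAK1, SLC38A3, CCL18, ETFDH, HSPA5, DUSP1, TNC and KLF6 ended in 8 to 19 such fits, with adjusted p up to 0.0943. Values at the floor of 49.5 limit folds of dim genes.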

Other observations

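The amino acid, glucocorticoid and p53 tests were set down before their results, on lists chosen after the data were seen; the genes SAT1, ALDH2, CRKL and GADD45A were also chosen after their values were seen.

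In 6 genes every dermatomyositis biopsy lay on one side of every normal biopsy, 4 above and 2 below, where chance gives 0.0073 genes above among all those tested. Beside CD163, CDKN1A and POSTN, the gene above was SAT1, the rate-limiting enzyme of polyamine breakdown (2.75-fold higher; adjusted p = 0.000299). Below were ALDH2, the mitochondrial aldehyde dehydrogenase (1.89-fold lower; adjusted p = 0.0075), and CRKL, an adaptor of tyrosine kinase signalling that acts at the neuromuscular junction (1.35-fold lower; adjusted p = 0.0028).

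Genes that answer a lack of amino acids through the transcription factor ATF4 were higher beyond ASNS and CHAC1. Of 18 other targets tested, 6 rose, among them PSAT1, an enzyme of serine synthesis (1.0 on the log2 scale; adjusted p = 0.0145), MTHFD2, a mitochondrial enzyme of folate metabolism (1.02; adjusted p = 0.0063), SLC3A2, the heavy chain of amino acid transporters (0.79; adjusted p = 0.0038), and DDIT4, an inhibitor of mTOR signalling (1.01; adjusted p = 0.0187). The score was higher by 0.53 (95% interval 0.25 to 0.81; permutation adjusted p = 0.00048; 11 of 13 patients above every normal biopsy), but camera with an estimated correlation did not call the list (adjusted p = 0.0748). An amino acid response may thus be active in the diseased muscle, though a member of the list, WARS1, is also induced by interferon, and the endoplasmic reticulum stress list holds others such as TRIB3.

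CDKN1A and GADD45A, which rose 9.99-fold and 4.66-fold, are targets of p53 among other inputs. Without the 3 unscaled arrays the log2 difference of CDKN1A was 2.65, against 3.32 with them. The score of 11 other p53 targets was higher by 0.28 (0.11 to 0.44; permutation adjusted p = 0.0036; 9 of 13 patients above every normal biopsy). Camera with an estimated correlation did not call this list either (adjusted p = 0.0748), and single members went both ways: ZMAT3 rose (0.59 on the log2 scale; adjusted p = 0.036) and SESN1 fell by 0.55 (adjusted p = 0.0301). A p53 response may be part of the picture.

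CD163 and metallothioneins are also induced by glucocorticoids, a usual treatment of the disease on which the labels say nothing. The score of 13 other glucocorticoid-induced genes differed by 0.22 (-0.24 to 0.68; permutation adjusted p = 0.33; 4 of 13 patients above every normal biopsy), and 2 passed, DUSP1 and CEBPD. The interval allows a rise as large as that of the ATF4 targets, so a missed threshold was too loose a bound to argue against treatment, and a glucocorticoid response cannot be told apart from none.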
